A study of Drosophila melanogaster with 10 samples.

How the data were processed

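Libraries were made from whole adult flies of mixed ages, separated by sex by hand and snap-frozen, per the labels' protocols. Per the labels, RNA bound by purified rabbit anti-UNR IgG or by non-specific rabbit IgG was eluted, DNase-treated and sequenced with the Solexa NlaIII tag protocol, and total RNA followed an RNA-Seq protocol. The deposited files list reads with their matches to the genome, so their unit is other than a count, a ratio or a level: the numeric columns give the number of matches of each read with each number of mismatches. Aligner, genome build and filters are not given in the sources used here. Positions are given on the 6 arms 2L, 2R, 3L, 3R, 4 and X, and no other sequence is named in the files.

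Reads were summed with the copy number in each read label. Of the reads in the RIP libraries (RNA immunoprecipitation), 20.3% to 29.9% were placed once, but only 2.33% to 4.62% without a mismatch. In total RNA 70.9% to 78.8% were placed once. Genome sequence was rebuilt from the total RNA reads placed once without a mismatch (37023415 bases), to read the bases before each tag. Of 50769442 bases compared between libraries 0 differed. This was fixed in advance, because such reads repeat the genome they were aligned to. Exact tags of known context lay right after CATG in 69.2% to 85.5% of cases in UNR IP. In male and female IgG it was 44.6% and 43.3%. Tags with 1 mismatch did so in 2.22% to 11.2% of cases. For this reason exact tags right after CATG were counted. This rule left out a larger share of the exact tags of known context in IgG than in UNR IP. The plan had named every read as the first choice and CATG tags as its alternative, and the order was exchanged from this check, before any test between groups. Adapter-derived tags, those sharing at least 10 bases with the adapter, were left out after the first fits had been seen.

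No genome or annotation of the build used in the files was at hand. The gene table at hand is of Release 6, and on 5 arms it has a gene that ends beyond the highest position in the files, so it was not used. Transcribed loci were stretches of pooled total RNA depth of at least 5, joined over gaps of up to 100 bases, at least 100 bases long, and linked by splice junctions with at least 3 reads. Junctions came from unplaced total RNA reads split with at least 15 bases on each side of an intron of 40 to 20000 bases. This gave 30243 loci with a median span of 465 bases, 5670 of them with a junction, from 11804 junctions. Tags were counted on the strand that held most of them in a locus. On 2472 loci with junctions of known strand, 91.7% of tags lay on the junction strand. A locus can be part of a gene or can join neighbouring genes.

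Counts were tested with limma-voom (limma 3.58.1, R 4.3.3) with trimmed-mean factors (trims 0.3 and 0.05) and a Benjamini-Hochberg threshold of 0.05, two-sided. The count filter asked for 15 counts in all. It also asked for the level of 10 counts at the median library size, in the main fits in at least 1 sample. A locus could thus enter the test through a single IgG library. The 6 RIP libraries shared a single fit with 4 groups, because each IgG group has 1 library, and that library is assumed to vary like the UNR IP pairs. The fit gave UNR IP over IgG per sex, the sex difference of the 2 ratios, and female over male UNR IP. The female total RNA libraries differed by a chi-square of 1.03 per degree of freedom over 22280 loci, against 4.51 over 17610 loci for the male libraries. They were summed as 1 sample, a choice made after the data were seen. Parts of 200 bases, tag sites and junctions sharing a splice site, each with at least 10 reads, were tested with limma's diffSplice and Simes p-values per locus or site. That test pools the spread over the parts, sites or junctions compared, which come from the same samples, so its p-values can be too small. Lists were compared with two-sided Fisher exact tests, adjusted over 11 tests. Parsing, counting and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

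Total RNA, male UNR IP over IgG, parts, tag sites and splice sites were tested on simulated data with a dispersion of 0.05. There were 200 changed loci, and fewer for tag sites and splice sites. Recovery was not simulated for female enrichment, the sex difference in enrichment, female against male UNR IP or UNR IP beyond total RNA. For total RNA the test found 7.46% of 2-fold, 61.2% of 4-fold and 95.5% of 8-fold changes. For UNR IP over IgG in males it found 1.49%, 29.9% and 84.8%, and with reduced IgG counts 0%, 5.97% and 40.9%. Libraries without enrichment were simulated from a single profile shared by both sexes and by UNR IP and IgG, with IgG tags in groups of 10. With IgG counts reduced by that known group size, 0 loci were called in males, in females or for their difference. Dividing by the simulated group size undoes the grouping, so this does not test the reduction on real libraries. For parts it found 14.5% of 8-fold and 13.5% of 32-fold changes. The 32-fold simulations were added after the data were seen.

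Named loci follow a rule fixed before the data were examined: among loci past the threshold whose libraries do not overlap between groups and whose highest group mean is at least 20 CPM, those with the largest change in each direction. At most 2 per direction are named, because loci have no gene names here. Exceptions are X_9947753, named as the X locus with most female reads, and the parts, splice sites and tag sites, named by their Simes p-value. Splice site 5947333 and the site in 3R_5167519 were chosen after their values were seen, and pass over 3R_7417030 and 3L_22858871, each with an intron of unknown strand, and 3R_16894742, all with smaller p-values than the site in 3R_5167519. Gene lists and genes named in the plan need gene names and were not analysed here.

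Alternatives were median-of-ratios factors, library size alone, no count filter, limma-trend with a prior count of 2, both strands or the tag strand alone, other sets of reads, the libraries of a single sex, higher count minimums, a replicate block, and leaving out each replicate. Added after the data were seen were the reduction of IgG counts to independent tags, IgG counts raised to the median occupied locus, crossed replicate numbers, adapter tags kept, exact reads in any context or in total RNA, CATG tags with up to 1 mismatch, parts on a single strand, the replicate block for tag sites, most alternatives of the overlap, X share and correlation, and the fits with the female total RNA libraries as 2 samples (unless with the replicate block or a replicate left out). Comparisons added after the data were seen were female against male UNR IP, UNR IP beyond total RNA, and splice sites. UNR IP beyond total RNA compared the estimates of separate limma fits, after the median difference over loci was taken off. A floor of 3 counts or 3 independent tags stands in for groups at 0.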

Results

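UNR is an RNA-binding protein that helps to set the output of the X chromosome in Drosophila melanogaster. The series addressed which RNAs UNR binds in adult males and females, and whether sex differences in binding go with sex differences in transcript level, splicing or untranslated regions. RNA was recovered from whole adult flies with antibody against UNR, in 2 libraries per sex, or with non-specific rabbit IgG, in 1 library per sex. These 6 libraries were read as tags of 15 to 17 bases, with a protocol whose tags start right after an NlaIII site (CATG). Exact tags of known context did so in 69.2% to 85.5% of cases in UNR IP, and in 44.6% and 43.3% in male and female IgG. Total RNA was read as 40-base reads in 2 libraries per sex. The male UNR immunoprecipitation (UNR IP) libraries held 14117394 and 14945399 reads, the female ones 15190639 and 15265278, the male IgG library 10345441 and the female IgG library 12390343. Tags counted in transcribed loci were 143386 and 70471 in male UNR IP, 309133 and 228070 in female UNR IP, 76677 in male IgG and 86241 in female IgG. The total RNA libraries held 22973938 and 6929630 reads in males and 15413009 and 17234940 in females.

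The female total RNA libraries differed by about the sampling noise (chi-square 1.03 per degree of freedom) and were counted as 1 sample, so error is given for the male libraries only (SD, n = 2). Loci were built from the total RNA reads because the files do not pair positions with gene names. Each locus is named by its chromosome arm and first position in the deposited alignments. The genome build is not given in the sources used here, nor is it stated whether positions count from 0 or from 1. The labels do not say that replicates came from separate groups of flies, so p-values measure the spread between samples. Those for parts, splice sites and tag sites pool that spread within a locus or site and can be too small. Intervals and floors cover counting error only.

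Total RNA addressed the question of sex-specific transcript levels, and most loci differed between the sexes. Of 28445 loci tested, 14323 were higher in females and 8811 in males, and 12594 and 7390 of these differed by at least 1 on the log2 scale. The 2 loci with the largest female excess were neighbours on X. Locus X_8375667, which ends at 8377446, had 4806 CPM (counts scaled to a common library total) in females and 0.715 ± 0.0403 in males, a log2 difference of 12.65 (SE 0.26, limma adjusted p = 0.000856). Locus X_8373268, which ends at 8374550, had 3312 CPM in females and 0.467 ± 0.134 in males (log2 12.49, SE 0.34, limma adjusted p = 0.000856). In males, 2L_10642564 (end 10643099) reached 111 ± 17.3 CPM and 2R_4905367 (end 4906489) 112 ± 2.34 CPM, and neither had a read in the female sample. Against a floor of 3 female reads they were at least 887-fold and at least 895-fold higher in males (limma adjusted p = 0.00751 and 0.0024). The tests were two-sided, and the single female sample was assumed to vary like the male pair. With only the reads on the strand of the tags, which also leaves only the 7610 loci with tags, 6324 loci passed the test. Of these 3153 were higher in females (49.9%), against 61.9% over all loci and both strands.

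The X chromosome carried a large part of the female excess. Of 6438 X loci, 69.1% were higher in females and 16.6% in males, with a median log2 difference of 2.49. Medians on the other arms lay between 0.13 (2L) and 0.55 (3L), and the median over all loci was 0.71. X loci were more often female-higher than loci elsewhere (odds ratio 2.75, 95% interval 2.59 to 2.92, two-sided Fisher exact p = 1.06e-262, adjusted p = 1.17e-261 over 11 such tests) and less often male-higher (odds ratio 0.366, interval 0.341 to 0.394, p = 9.06e-193, adjusted p = 3.32e-192). X took 14.4% and 14.8% of the placed reads in the male libraries and 24.2% in the female sample. The 5 X loci with most female reads held 6.66% of them, and 0.224% and 0.259% of the male reads. The highest was X_9947753 (end 9949585), with 28080 CPM in females and 867 ± 62.1 in males. With those 5 loci left out, X held 18.7% of the female reads and 14.2% and 14.6% of the male reads. Loci with a splice junction made up 17.1% of the female-higher loci and 26.1% of the male-higher loci (odds ratios against the other loci 0.697 and 1.70, adjusted p = 1.96e-33 and 1.16e-64). Loci are not independent replicates, so these odds ratios describe the lists.

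**Figure D1:**
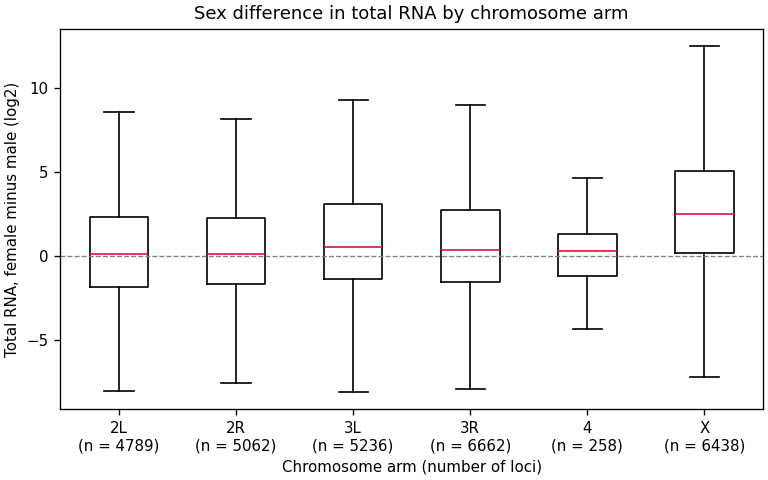
Log2 female over male difference in total RNA per locus, by chromosome arm, as boxes of the quartiles with the median as a line, whiskers as drawn by matplotlib's default, and outlying loci not drawn. The median is 2.49 on X and 0.13 to 0.55 on the other arms.

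Within loci, total RNA was also distributed differently along the transcript. The test of parts pools its spread over the parts of a locus, all from the same samples, so its p-values can be too small. Of 22616 loci divided into 200-base parts, 2582 (11.4%) used their parts differently in the 2 sexes. In 2R_16521521 (end 16527948), the part from 16525716 to 16525915 held 288 of 2097 male reads and 9 of 3088 female reads, a relative log2 difference of -7.11 (Simes adjusted p = 1.7e-17, limma). In 3R_5167519 (end 5186549), the part from 5182896 to 5183095 held 905 of 10842 male reads and 22 of 14186 female reads (relative log2 -6.19, Simes adjusted p = 4.26e-16, limma). Orientation was taken from the strand with more tags, however few, and can be wrong. In 3L_8983655, all 8 junction reads of known strand lay on the other strand. It was set in this way for 7590 loci with 2 or more parts. Among them the 3′-most part passed the test in 952, with 574 higher in males and 378 in females. Over the 7590 loci, the last part less the first had a median log2 female over male difference of -0.271. Such a shift over all loci was not told apart from changes in single loci. A locus can join neighbouring genes, and 1704 of 6071 loci with tags and junctions on a single strand passed. The count was 4920 with the female libraries as 2 samples, though that pair differed by about the sampling noise.

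Splice junctions differed as well, a result added after the data were seen. Of 166 splice sites joined to more than 1 partner, 31 were used differently between the sexes. From 5947333 in locus 2L_5943774, the intron to 5947856 took 12.1% ± 5.36 of the male junction reads and 83.6% of the 67 female ones (exact Clopper-Pearson 95% interval 72.5% to 91.5%). The intron to 5948406 took 87.9% ± 5.36 in males and 16.4% in females (Simes adjusted p = 3.43e-07, limma). Locus 3R_5167519, whose male-rich part is described with the parts of loci, also had a male-rich junction. The intron from 5183178 to 5183705 took 30.1% ± 4.53 of the male reads at that site and 0 of 85 female reads, which allows up to 3.53% by the floor of 3 counts and 4.25% by the exact Clopper-Pearson interval (Simes adjusted p = 6.35e-05, limma). With a minimum of 50 reads per junction, 12 of 23 sites passed. In simulated data the test found 4% of 8-fold and 56% of 32-fold changes.

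The libraries from the precipitations followed their sex labels. The 1577 loci limited to males in total RNA took 29.4% and 25.9% of the male UNR IP tags and 29.2% of the male IgG tags. They took 0.0815% and 0.0881% of the female UNR IP tags and 0.204% of the female IgG tags.

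RNA recovered with UNR differed between the sexes mostly where total RNA differed, a comparison added after the data were seen. Of 2654 loci tested, 518 were higher in female UNR IP and 810 in male UNR IP. Of the male-higher loci that total RNA also covered, 733 were male-higher in total RNA, 47 passed no test there and 29 were female-higher. Of the female-higher ones, 442 were female-higher in total RNA, 56 passed no test and 19 were male-higher. An example is 3R_14676768 (end 14677530), with 1641 ± 174 CPM in male UNR IP and 4.38 ± 6.2 in female UNR IP (SD, n = 2 each), and 288 ± 45.7 and 0.25 CPM in total RNA of males and females. The log2 sex differences in UNR IP and in total RNA correlated across 2651 loci with r = 0.855 and rho = 0.804, where loci are not replicates. In the IgG libraries r was 0.556, and in UNR IP libraries thinned to the same number of occupied loci it ran from 0.548 to 0.603 over 100 draws. Female-higher loci were 39.0% of those passing the limma test, and 54.2% (779 against 658) when libraries were scaled by size alone, which moved the median from -0.23 to 0.31. With every read placed once the majority also turned, with 806 loci higher in females and 715 in males. Without a count filter 753 and 1253 passed, and without female UNR IP replicate 2 it was 229 and 498.

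**Figure D2:**
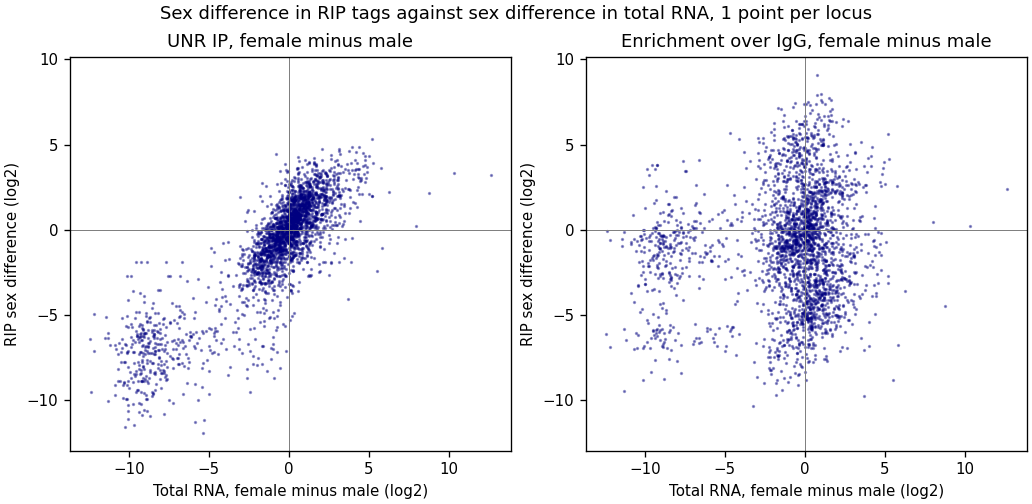
Log2 female over male difference in UNR IP (left) and in enrichment over IgG (right) against that in total RNA, with 1 point per locus. Across 2651 loci r is 0.855 for UNR IP and 0.123 for the enrichment.

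UNR IP exceeded or fell short of the total RNA sex difference at 391 loci, also a test added after the data were seen. Excess was measured from the median locus, where the sex difference in UNR IP less that in total RNA was 0.083 on the log2 scale. It was towards females at 142 loci and towards males at 249 (two-sided, from the estimates of separate limma fits for UNR IP and total RNA). This count rested on the female libraries: it was 214 without female UNR IP replicate 1. Without replicate 2 it was 3, with 461 loci at an unadjusted p under 0.05.

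The IgG libraries, against which enrichment is measured, reached fewer loci than the UNR IP libraries. Adapter-derived tags made up 46.5% of male and 27.6% of female IgG tags, against 0.65% to 3.3% in UNR IP. IgG tags fell in 1630 loci in males and 1783 in females, against 4311 to 5122 in the UNR IP libraries. A UNR IP library of the same sex, thinned, reached as many loci with 7446 tags in males and 9585 in females. If IgG tags fall on loci as UNR IP tags do, they came in groups of about 10.3 and 9.0 per independent tag. That condition was not tested, and IgG RNA confined to fewer loci would mean smaller groups. On that estimate, levels of 0 in IgG lie under a floor of 3 independent tags, 403 CPM in males and 313 CPM in females, a floor chosen after the data were seen.

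In males, the question was which RNAs UNR IP enriched over IgG, and 1258 of 2654 loci were higher in UNR IP and 156 lower. Locus 3R_228787 (end 232902) came first, with 3142 ± 212 CPM in UNR IP and no tag in IgG, at least 7.80-fold above the IgG floor (limma adjusted p = 1.07e-08). Its main tag, AATGAAATATAACTTGA, lies at 232850, near the end of the locus. Locus 3R_14676768 had 1641 ± 174 CPM and no IgG tag, at least 4.07-fold (limma adjusted p = 1.6e-07). Among the lower loci, 2L_22931089 (end 22931589) had 37 tags in IgG (482.5 CPM) and none in either UNR IP library, and 2L_7031283 (end 7032178) had 29 IgG tags (378 CPM, under the IgG floor) and none in UNR IP (limma adjusted p = 3.53e-06 and 9.72e-06). Neither lower locus had a tag in the female libraries, so both entered the test only through male IgG. The total of 1258 is not taken as a count of bound RNAs. Simulated libraries with no enrichment but IgG tags set in groups of 10 gave 1018 higher loci and 131 lower ones. Their group size rests on the untested estimate for IgG, and they shared a single profile over both sexes. With IgG counts reduced to independent tags, a step added after the data were seen, 136 loci were higher and 60 lower (246 higher without male UNR IP replicate 1 and 387 without replicate 2), and the other scalings turned the majority, to 14 higher and 48 lower with median-of-ratios factors and 14 and 148 with library size alone (median log2 ratio 0.36, -0.33 and -0.90).

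Before that reduction, 89.0% of the male loci passing the test were higher in UNR IP, 78.9% with median-of-ratios scaling (955 higher, 256 lower) and 62.7% with library size alone (772 higher, 460 lower). The median log2 ratio moved from 1.81 to 1.10 and 0.57. With every read placed once, most of them with a mismatch, 542 male loci were higher and 665 lower. Without female UNR IP replicate 2, which shares the estimate of spread, 712 were higher, and 541 were with the male libraries alone. Loci 3R_228787 and 3R_14676768 passed the test with reduced IgG counts (limma adjusted p = 7.18e-05 and 0.00103), and also with library size alone on top of it (0.00258 and 0.00899).

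In females, the same question gave 925 loci higher in UNR IP and 285 lower. Locus 3R_25680432 (end 25683169) had 1865 ± 15.2 CPM in UNR IP and no IgG tag, at least 5.96-fold above the IgG floor (limma adjusted p = 4.14e-08). Locus 3R_19989744 (end 19993867) had 1155 ± 46.5 CPM and no IgG tag, at least 3.69-fold (limma adjusted p = 2.37e-07). Loci 2L_10270101 (end 10272204) and 3L_15804330 (end 15804539) each had 34 tags in IgG (394 CPM) and none in UNR IP (limma adjusted p = 2.37e-07). Neither of these lower loci had a tag in the male libraries, so both entered the test only through female IgG. The simulated libraries with no enrichment and IgG tags set in groups gave 947 higher loci and 124 lower ones. With IgG counts reduced to independent tags, 208 loci were higher and 477 lower, so the majority turned. Median-of-ratios scaling then gave 98 higher and 517 lower, and library size alone 68 and 729 (median log2 ratio -0.22, -0.61 and -1.02). It was 401 and 598 without male UNR IP replicate 1, and 382 and 611 without replicate 2.

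Without the reduction, library size alone gave 734 female loci higher and 566 lower, 56.5% against 76.45%, and moved the median log2 ratio from 0.54 to -0.26. It was 0.16 with median-of-ratios scaling. With every read placed once 633 were higher and 674 lower. Without female UNR IP replicate 2, 461 were higher, with limma-trend 590, and with the female libraries alone 225. Loci 3R_25680432 and 3R_19989744 passed the test with reduced IgG counts (limma adjusted p = 9.59e-05 and 0.000902), also with library size alone (0.00156 and 0.00811).

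**Figure D3:**
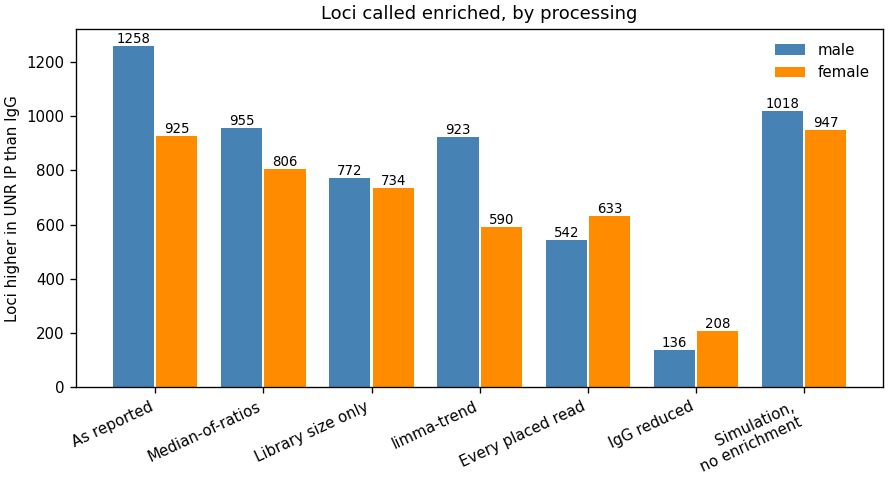
Number of loci higher in UNR IP than in IgG, by sex (bars) and processing. At the right are simulated libraries that hold no enrichment, with IgG tags set in groups of 10. The counts of 1258 in males and 925 in females fall to 136 and 208 with reduced IgG counts, and the simulation gives 1018 and 947.

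The enriched lists of the 2 sexes overlapped. Of the loci higher in UNR IP, 560 were on both lists, where lists drawn independently would share 438.5 (odds ratio 2.27, 95% interval 1.92 to 2.68, two-sided Fisher exact adjusted p = 5.72e-23). Both lists came from the same fit, with a shared spread per locus, so the calls are not independent and these values only describe the lists. The overlap was not counted in the simulated libraries without enrichment. With reduced IgG counts 38 loci were on both lists, and 4 with library size alone as well. The share of X loci on the lists did not differ from that of the other loci beyond chance in either sex. X loci were 15.1% of the male list and 16.98% of the other loci (odds ratio 0.87, interval 0.702 to 1.08, exact p = 0.204, adjusted p = 0.25). They were 17.4% of the female list and 15.4% of the other loci (odds ratio 1.16, interval 0.929 to 1.44, exact p = 0.184, adjusted p = 0.25). With reduced IgG counts the odds ratios were 1.07 in males (exact p = 0.811) and 1.49 in females (exact p = 0.0301, not adjusted). Without male UNR IP replicate 1 the male ratio was 1.18 (exact p = 0.156).

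The difference in enrichment between the sexes was tested directly, as the study asked for sex-specific binding, and 1027 loci passed. Enrichment over IgG was higher in females at 315 and in males at 712. Locus 3R_20639890 (end 20642640) had 936 ± 308 CPM in female UNR IP and no tag in female IgG, at least 2.99-fold, and 148 ± 28.1 CPM in male UNR IP with 55 tags (717 CPM) in male IgG. Its log2 difference was 9.08 (SE 1.12, limma adjusted p = 4.76e-06). Locus 3L_21166205 (end 21168239) differed likewise, by 7.96. With reduced IgG counts these differences were 6.02 and 4.87 (limma adjusted p = 0.00845 and 0.0144), and the adjusted p were 0.0265 and 0.0474 with library size alone on top. Towards males, 3R_5609192 (end 5610166) differed by -10.31, with 56.0 ± 39.1 CPM in male UNR IP, under the IgG floor, 1.62 ± 2.29 in female UNR IP, no tag in male IgG and 28 in female IgG. Locus 3L_2268847 (end 2270508) differed by -9.76, with 45.8 ± 15.5 CPM in male UNR IP, also under the floor, 3.23 ± 4.58 in female UNR IP, no tag in male IgG and 30 in female IgG. With reduced IgG counts the male-higher loci passed with -7.17 and -6.54 (limma adjusted p = 0.00951 and 0.0113), and with library size alone on top the adjusted p were 0.0487 and 0.0712. Without female UNR IP replicate 2, limma called 0 loci, with 868 at an unadjusted p under 0.05. Simulated libraries without enrichment, with grouped IgG tags and a single profile for both sexes, gave 424 female-higher and 515 male-higher loci.

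With IgG counts reduced to independent tags, 8 loci had higher enrichment in females and 187 in males. Of these calls, median-of-ratios scaling left 0 (495 at an unadjusted p under 0.05, limma) and library size alone gave 22. Without male UNR IP replicate 1 the reduced counts gave 430 loci and without replicate 2 they gave 435. Unreduced, limma-trend gave 457 loci (136 female-higher, 321 male-higher), and every read placed once gave 188 female-higher and 134 male-higher, a turned majority. The median log2 difference was -0.85, -0.53 with median-of-ratios scaling and -0.40 with library size alone.

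Set against total RNA, the sex difference in enrichment followed transcript levels weakly, with r = 0.123 and rho = 0.0725 across 2651 loci. The male-higher enrichments held 313 loci male-higher in total RNA and 287 female-higher ones (odds ratio 0.916, interval 0.768 to 1.09, exact p = 0.333, adjusted p = 0.366). The female-higher enrichments held 123 loci female-higher in total RNA and 135 male-higher ones (odds ratio 1.00, exact p = 1). The value of r depends on how the IgG level is set: it was 0.613 with reduced IgG counts and 0.811 with IgG counts raised to the median occupied locus. It was 0.0265 without male UNR IP replicate 1, 0.0694 without female replicate 1, and 0.0463 over loci with a mean of at least 50 tags.

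Loci with more than 1 NlaIII site were compared for the site that held the tags, as a shift between sites can come from an alternative 3′ end or from neighbouring genes joined in a locus. Of 474 such loci, 22 used their sites differently in male and female UNR IP. In 3R_7795822 the tag ACTAGAGAAATTGTATG at 7797386 took 18.1% ± 2.68 of the tags in males and all 169 tags in females. The tag GACTGTGTAAATAGGAC at 7798426 took 81.9% ± 2.68 in males (Simes adjusted p = 1.3e-07, limma, n = 2 per sex). In 2R_16554960 the tag TAGATTGTTGATTAATT at 16556004 took 64.1% ± 28.4 in males and all 461 tags in females, and ATCCTGGAGTCGTTGAA at 16557262 took the remaining 35.9% (Simes adjusted p = 6.83e-05, limma). The 3′-most site was higher in females at 14 loci and in males at 8. Without female UNR IP replicate 1 the count was 1, and without male UNR IP replicate 2 it was 35. In simulated data the test found 0% of 8-fold and 55% of 32-fold changes.

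**Figure D4:**
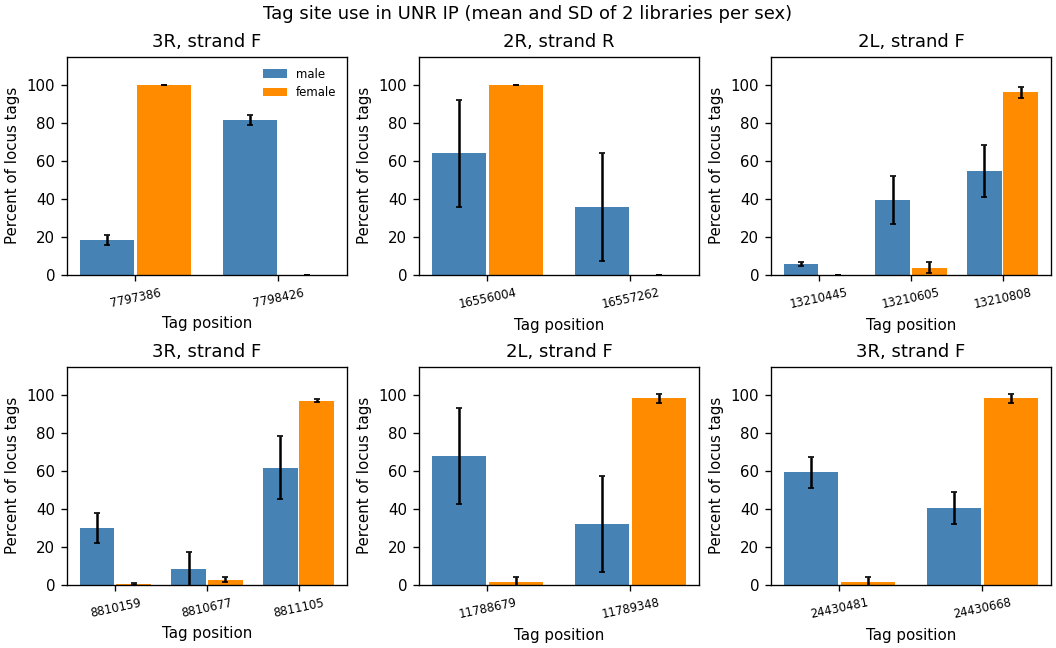
Percent of each locus's UNR IP tags at its NlaIII sites, as mean and SD of 2 libraries per sex, for the 6 loci with the smallest Simes p-values, titled by arm and tag strand. The site at 7798426 on 3R takes 81.9% of the tags in males and none of the 169 tags in females.

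A few tags without an exact place on the 6 arms took much of each UNR IP library. They were picked for a larger share in every UNR IP library than in either IgG library. The tag ATCTGAGTTCAAACCGG made up 18.65% and 13.5% of male UNR IP, 14.1% and 13.3% of female UNR IP, 2.81% of male IgG and 5.34% of female IgG. The tag TAAGAATTTAAAAGTCG took 15.9% and 16.2% of male UNR IP, 10.3% and 14.7% of female UNR IP, 2.34% of male IgG and 4.12% of female IgG.

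**Figure D5:**
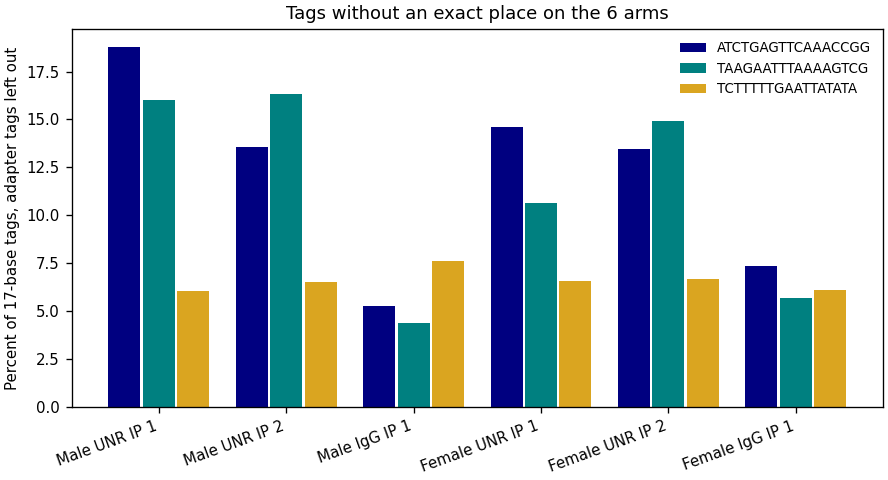
Percent of 17-base tags taken by 3 tags without an exact place on the 6 arms, per library, with adapter-derived tags left out of the total. On this scale ATCTGAGTTCAAACCGG takes 13.45% to 18.8% of UNR IP tags and 5.25% and 7.37% of male and female IgG tags.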

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

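Of the tests in this part, those on the scaling of the libraries, on adapter reads and on reduced IgG counts were chosen after the results were seen.

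The enrichment of RNA by UNR over IgG differed between males and females at 1027 loci in the direct test of the difference, and at 0 without female UNR IP replicate 2 (868 at an unadjusted p under 0.05 in limma). The 4 named loci differed by 9.08 (3R_20639890), 7.96 (3L_21166205), -10.31 (3R_5609192) and -9.76 (3L_2268847) on the log2 scale. In each, 1 of the IgG libraries had no tag, and with reduced IgG counts the values were 6.02, 4.87, -7.17 and -6.54. Male UNR IP lay under the male IgG floor in all 4.

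Most of those loci, 712 of 1027, had the higher enrichment in males. Scaling of the libraries stays open: the male share was 61.5% (exact 95% interval 58.4% to 64.6%) with library size alone, but that scaling still left the median of all loci at -0.40, and with every read counted the majority turned (188 towards females, 134 towards males). A small number of RNA molecules in the IgG libraries remains a candidate cause. Of the male-higher enrichments, 32.2% were also higher in male UNR IP. Over all tested loci 810 of 2654 were, a similar share, so this value cannot tell that cause from others. Simulated libraries with no enrichment had IgG tags set in groups of 10 and a single profile for both sexes. They gave 424 loci towards females and 515 towards males. Reducing their IgG counts by that known group size gave 0 loci, but this undoes the simulated grouping. It is therefore no reference for the data, where the group size is an estimate and the sexes differ. With reduced IgG counts the data gave 8 and 187, or 3 and 19 with library size alone on top. Sex-specific binding by UNR stays open, untested apart from these values.

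The sex difference in UNR IP followed that in total RNA with r = 0.855. RNA carried through the precipitation without UNR may account for this, since the IgG libraries, which lack the UNR antibody, reached r = 0.556, within the range of 0.548 to 0.603 of UNR IP libraries thinned to the same number of loci. Binding by UNR in proportion to transcript level was not tested and stays open for UNR IP beside such carry-through.

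Some tags without an exact place on the 6 arms took a larger share of every UNR IP library than of either IgG library. They were picked by this rule among tags that reached 1% of a library, so the excess itself is no test. Some of them differ by a single base from a more abundant one, and whether these come from separate RNAs was not tested. The tag ATCTGAGTTCAAACCGG made up at least 13.3% of each UNR IP library, against 2.81% and 5.34% of male and female IgG. Adapter reads in IgG are argued against as the whole cause, because without them the lowest UNR IP share was still 1.825 times the highest IgG share. RNA of the flies from sequence outside the 6 arms is a candidate source. Total RNA reads without a place held the tag after CATG at no less than 38.1 RPM (scaled to all reads of a library). No identity was assigned to it, and binding by UNR was not tested.

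The tag TAAGAATTTAAAAGTCG took at least 10.3% of each UNR IP library, TCTTTTTGAATTATATA 6.01%, TAAGAATTTAAAAGCCG 0.759%, ATCTGAGTTAAAACCGG 0.661%, ATCTGAGTTCAAACAGG 0.518% and TTTTTGTTAAACAGGCG 0.505%, each above its share of both IgG libraries. Without adapter reads, TCTTTTTGAATTATATA and TTTTTGTTAAACAGGCG had a lowest UNR IP share of 0.795 and 0.856 times the highest IgG share. Within a sex, TTTTTGTTAAACAGGCG was then still above IgG in all 4 UNR IP libraries, and TCTTTTTGAATTATATA in both female but neither male one.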

How the results depend on the processing

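Chosen after the results were seen were reduced and raised IgG counts, crossed replicate numbers, adapter tags kept, exact reads, tags with up to 1 mismatch, female total RNA libraries as 2 samples (unless with the replicate block or a replicate left out), parts on a single strand, the replicate block for tag sites, all alternatives of the comparisons added later, those of the overlap except library size and a log2 minimum, those of the X odds ratio except a log2 minimum and a matched background, and those of the correlation except the tag minimum and leaving out replicates. Over 16 results, 124 of 176 alternative values showed no change by the rule for their kind: for counts, a total within 1.5 times, whichever way the majority went; for odds ratios, the same direction and side of an unadjusted p of 0.05; for the correlation, a shift within its bootstrap SD. Among those counts the majority turned in female against male UNR IP with library size alone (779 and 658) and every read (806 and 715), and in female enrichment with every read (633 and 674). The causes of the changes were not tested unless stated.

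Loci enriched in males (1258) numbered 772 with library size alone, 542 with every read placed once, 541 with that sex's libraries alone, 136 with reduced and 269 with raised IgG counts, and 712 to 1315 on leaving out a replicate. In females (925) they numbered 590 with limma-trend, 225 with that sex's libraries alone, 208 with reduced and 247 with raised IgG counts, and 461 to 1025. The sex difference in enrichment (1027) gave 457 with limma-trend, 322 with every read placed once, 680 with crossed replicate numbers, 195 with reduced and 576 with raised IgG counts, and 0 to 1099 (0 without female UNR IP replicate 2, with 868 at an unadjusted p under 0.05 in limma). With the male or female libraries alone, fewer samples set the spread.

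With reduced IgG counts, median-of-ratios scaling gave 14 male and 98 female loci and 0 sex differences (495 at an unadjusted p under 0.05 in limma). Library size alone gave 14, 68 and 22. Leaving out a replicate gave 119 to 387, 160 to 401 and 130 to 435.

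Female against male UNR IP (1328) gave 2006 without a count filter, where more loci were tested, and 727 to 1068 on leaving out a replicate. The excess over total RNA (391) ran from 3 to 331 on leaving out a replicate. The X odds ratio in males (0.87) turned to 1.07 with reduced IgG counts (exact p = 0.811) and ran from 0.928 to 1.18 on leaving out a replicate, 1.18 without male UNR IP replicate 1. In females (1.16) it was 1.49 with reduced IgG counts (exact p = 0.0301, not adjusted). The correlation with total RNA (0.123) was 0.157 with every read placed once, 0.0463 with a mean of at least 50 tags, 0.613 with reduced and 0.811 with raised IgG counts, and 0.0265 to 0.14 on leaving out a replicate. The overlap of the lists kept direction and call under all 12 of its alternatives, with odds ratios from 2.20 to 11.1. Because both lists come from a shared fit, this does not test shared binding.

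Total RNA (23134) gave 6324 on the tag strand alone, where fewer loci were tested, and 20259 to 24008 on leaving out a replicate. Parts of loci (2582) gave 1704 for loci on a single strand, of fewer tested, 4920 with the female libraries as 2 samples, 6621 and 6854 in that fit without male replicate 1 or 2, and 1991 to 6854 over all replicates left out. Splice sites (31) gave 12 with at least 50 reads, of fewer tested, and 24 to 32. Tag sites (22) ranged from 1 to 35 on leaving out a replicate.

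The labels do not pair the replicates. With the replicate block, tag sites gave 43. With the female libraries as 2 samples, total RNA gave 22430 with the replicate block and 22833 without it. The differences between replicates 1 and 2 correlated between the sexes with r = 0.21 in UNR IP and 0.01 in total RNA.

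Not run were gene lists, which need gene names, the named genes of the plan, all alignments, since reads placed more than once carry no position, and sums over untranslated and coding regions, which need an annotation. Leaving out a male total RNA library needs the female libraries as 2 samples, since the merged fit then has no residual degrees of freedom. The spread is then set by the female pair alone, which differed by about the sampling noise. In simulated data, 8-fold changes were found at 0% of tag sites and 4% of splice sites. At those with at least 200 reads it was 0% of 41 and 50% of 4.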

Other observations

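The comparison of base content with reduced IgG counts was chosen after the result was seen.

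The 1976 loci limited to females in total RNA held 4.15% of the female total RNA reads, and 0.857% and 0.736% of the female UNR IP tags and 0.68% of the female IgG tags. The 1577 male-limited loci held 13.3% and 12.5% of the male total RNA reads, and 29.4% and 25.9% of the male UNR IP tags and 29.2% of the male IgG tags. The lists come from total RNA, and tags need an NlaIII site, so the assays are not on the same scale, and no difference in recovery was tested.

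Only total RNA reads without a place were searched for the tags, so reads placed on the arms are missed in these rates. In them, ATCTGAGTTCAAACCGG and TAAGAATTTAAAAGTCG stood right after CATG at 38.1 to 41.4 and 52.2 to 57.8 RPM (scaled to all reads of a library). The tags ATCTGAGTTAAAACCGG and TAAGAATTTAAAAGCCG stood there at no more than 0.0871 and 0.174 RPM, although they took up to 1.59% and 1.46% of the male UNR IP tags. All 7 tags together took 44.9% and 41.1% of the male UNR IP, 33.3% and 38.6% of the female UNR IP, 9.76% of the male IgG and 14.9% of the female IgG tags. As each tag was picked for a larger share in UNR IP, this gap is no test. The tags that were rare among these unplaced total RNA reads each differ by a single base from a far more abundant tag among the 7. Whether they come from separate RNAs was not tested, so the 7 are not a count of RNAs.

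A hypothesis was that loci enriched in both sexes are rich in A. Matched on tag level, the 560 loci held 0.24 percentage points more A on the tag strand than the other loci (95% bootstrap interval -0.129 to 0.596), so the test decided neither way. With reduced IgG counts, the 38 loci held 0.866 points more (interval -0.496 to 2.4).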
